A study of Mus musculus with 2 samples.

How the data were processed

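Single cells of the hippocampus were profiled by droplet RNA sequencing in 57-week-old mice of a Fabry disease model. The GlaKO mouse lacks a working Gla gene, which encodes the lysosomal enzyme alpha-galactosidase A, and its littermates labelled wt served as controls. The series holds 2 libraries, 1 of each genotype, and the number of animals behind a library is not listed. Per the labels' protocols, mice were perfused with saline, the dissected hippocampi were dissociated with enzymes, debris was removed on a density gradient, and dead cells were sorted out with the dye 7-AAD. Each of these steps can change which cell types reach a library and in what state. Per the labels' protocols, 10000 cells per sample were loaded, 3' libraries were made with Chromium version 3.1 chemistry, and a pool was sequenced on a NovaSeq instrument.

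The values deposited by the authors are raw counts, one whole number of unique molecular identifiers (UMIs) per gene and cell barcode, and were used as they stand. The submitters' processing notes name Cell Ranger 6.0.1, R 4.1.3, Seurat 4 and the genome build mm10, and the labels' protocols name Cell Ranger 4.0 for demultiplexing. The gene annotation and the filters on cells and genes are not given in the sources used here. The smallest number of genes in a barcode was 982 in the wt and 988 in the GlaKO library. No gene was seen in fewer than 6 wt or 7 GlaKO cells, and only 97 of the wt and 125 of the GlaKO genes were seen in fewer than 60. Barcodes and genes had therefore been filtered before deposit. The wt library listed 13008 genes and the GlaKO library 13154. The 12744 genes listed in both were compared, and the 264 listed for wt alone and 410 for GlaKO alone were left out of ratios.

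Depth was 31929688 UMIs over 5443 barcodes in the wt library and 29914106 UMIs over 4572 barcodes in the GlaKO library. Barcodes with under 500 genes or over 20% mitochondrial UMIs were to be left out, and none met either limit. Scrublet, as built into scanpy 1.11.5, marked 26 wt barcodes (0.478%) and 59 GlaKO barcodes (1.29%) as doublets. These were removed, but at under 0.5% the caller cannot be said to have worked in the wt library, so an added alternative removed the 4% of barcodes with the highest doublet score. That left 5417 wt and 4513 GlaKO cells.

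Both libraries were clustered together in scanpy without batch correction: scaling to 10000 counts per cell, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0. Mitochondrial, ribosomal protein, immediate-early, heat-shock, erythroid and sex-linked genes took no part in clustering. A cluster was named only if at least 3 markers of a type, out of marker lists fixed before the data were examined, had UMIs in at least 10% of its cells, their mean log2 fold over the median cluster was at least 1.0, and its 10 leading genes did not hold as many or more markers of another type. Clusters 6 (706 wt and 245 GlaKO cells, choroid plexus epithelium) and 20 (34 and 47, border macrophages) had no marker of any type among those 10 genes, which in cluster 20 were led by Cd74, H2-Ab1 and H2-Aa, so these names rest on 6 and 3 detected markers. The condition on markers of another type applied only where the leading genes held such a marker. The limits of the naming rule were set after the clusters were seen. Names are written as types, with "-like" understood, and 1 cluster with leading genes of mixed types stayed unnamed (45 wt and 35 GlaKO cells).

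UMIs were summed per library and class and divided by the class total. A gene was compared in a class if its summed count reached 100, and a class was compared if each library held at least 100 of its cells. The log2 ratio of GlaKO over wt has an exact conditional 95% interval, summed counts have exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. These cover counting error only: with 1 library per genotype no test is possible, no p-value was computed, and every difference is one between 2 libraries. The intervals also take UMIs as independent, so a gene whose UMIs sit in a few cells has a true error wider than printed.

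For gene lists fixed before the data were examined, the median log2 ratio over measured members was set among 10000 random lists of the same size matched on mean expression. A list with at least 5 measured members was described where its median lay outside the middle 95% of random lists and at least 50% of its members reached 10% of their level in the class with the highest level, a guard against RNA released by other cells. That held for 32 pairs of list and class out of 153. Of the 153 pairs, 55 lay outside the middle 95% before the guard, against 7.7 expected if all genes and pairs varied independently. Lists hold genes that can vary together, share members and recur over classes of the same libraries, so 7.7 does not bound chance. Named genes were, by a rule fixed beforehand, the 10 highest and 10 lowest ratios in the 2 most numerous classes and the 5 highest and 5 lowest in the other compared classes. They had to pass the same guard, have an interval excluding a ratio of 1 and keep their direction after TMM scaling (edgeR 4.0.16 in R 4.3.3). Mitochondrial, ribosomal protein, sex-linked, erythroid and unnamed gene models were left out. Gla, the highest and lowest members of described lists, and genes at least 1.5-fold apart in one direction in every compared class were named as well. Some genes that this rule takes are not reported here.

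The ratio and list steps were tested on simulated counts with 200 genes changed by known folds. These were Poisson draws around a level shared by both libraries, the model that the intervals assume. They hold no UMIs gathered in few cells, no spread between libraries and no genes that vary together. The simulation therefore checks the computation and not the error in the real data. For the choroid plexus class (9425 genes), 95.6% of intervals held the true ratio and 60 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold had an interval excluding 1 on the right side. For the T cell class (2506 genes), these numbers were 95.6%, 51 of 67, 65 of 67 and 66 of 66. Of 100 unchanged lists per class, 2 and 3 lay outside the middle 95%.

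Alternatives fixed beforehand covered the cell filter, doublets, the Leiden resolution (0.5 and 2.0), clustering each library alone, the scaling of sums, equal weight for each cell, thinning every cell to 1000 UMIs, the count minimum (20 and 500) and the guard (30%). Added after seeing the data were the removal by doublet score, equal weights for the clusters of a class, an equal split of each class over 5 parts of UMI depth, and the removal of single cells. Gene positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.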

Results

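Cells of the hippocampus were compared between 1 wt and 1 GlaKO library from 57-week-old littermate mice by 3' single-cell RNA sequencing with UMIs. The title of the series concerns anxiety-like behaviour and hippocampal activity in this Fabry disease model, and the comparison asks how the cells of the hippocampus differ where alpha-galactosidase A is missing. A wt barcode held a median of 5054 UMIs from 2091 genes and a GlaKO barcode 6101 UMIs from 2464 genes. With 1 library per genotype there were no replicates and no test, and each interval given here is a 95% interval for counting error. Members of a gene list are counted by the sign of their ratio, and a second count gives those whose own interval excluded equal levels in that direction.

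Gla transcripts were lower in the GlaKO library but were not gone. Over all cells Gla had 396 UMIs in the wt library, or 12.5 CPM (counts scaled to the library or class total), and 220 UMIs, or 7.48 CPM, in the GlaKO library. The GlaKO level was 50.7 to 70.9% of wt, with a log2 ratio of -0.74 (-0.98 to -0.50). It was lower in oligodendrocyte precursors (log2 ratio -1.77, -2.68 to -0.92), in choroid plexus epithelium (-1.24, -1.76 to -0.75) and in microglia (-0.88, -1.56 to -0.20). In oligodendrocytes (-0.12), astrocytes (-0.26), neurons (0.27) and T cells (-1.10, from 8 and 6 UMIs) the interval included equal levels, so a difference was not detectable at this depth. Gla (ENSMUSG00000031266.6) lies on the minus strand of chromosome X at 134588149 to 134601125 (GRCm38). The main transcript has 7 exons, and its 3' untranslated region is in exon 7, at 134588149 to 134589869. No other annotated gene overlaps it. A 3' tag can lie outside the altered part of the gene, so these counts do not check the genotype. Thinning cells to 1000 UMIs moved the ratio to -0.84 in oligodendrocyte precursors and -1.93 in choroid plexus epithelium. TMM scaling moved the ratio over all cells to -0.99, while within classes it moved ratios by at most 0.085.

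**Figure D1:**
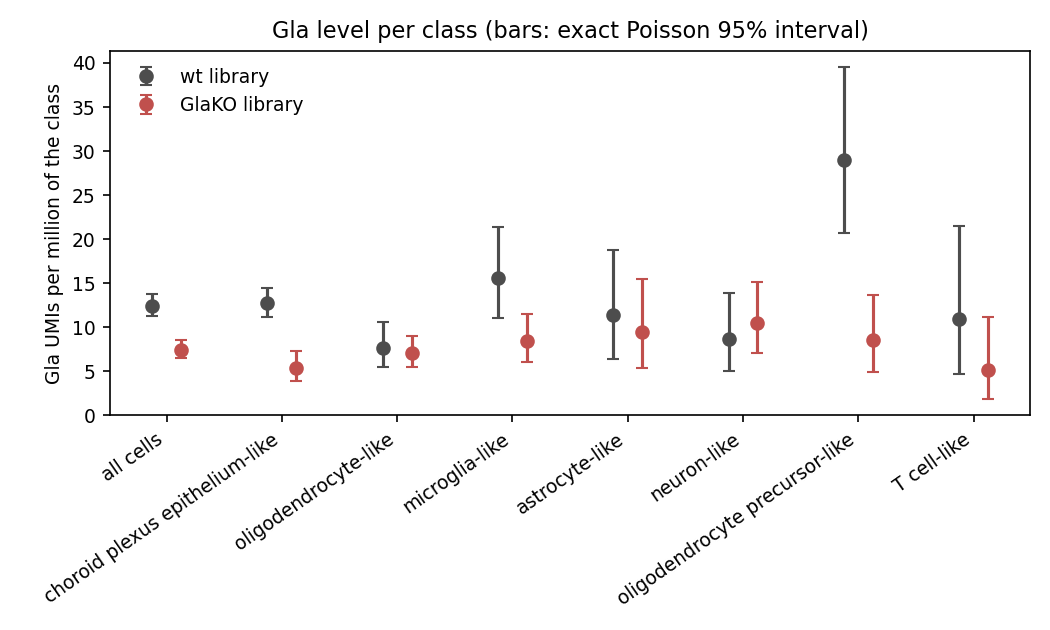
Gla level in CPM (vertical axis) over all cells and in each compared class, for the wt and the GlaKO library (1 library each); vertical bars are exact Poisson 95% intervals. The GlaKO point lies well below the wt point in oligodendrocyte precursors (8.52 against 29.0) and choroid plexus epithelium (5.40 against 12.7), while the intervals overlap in oligodendrocytes, microglia, astrocytes, neurons and T cells.

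Choroid plexus epithelium, the tissue that secretes cerebrospinal fluid, made up 47.8% of wt cells (2592 of 5417, 46.5 to 49.2%) and 17.8% of GlaKO cells (802 of 4513, 16.7 to 18.9%). Oligodendrocytes, which make myelin, were 15.7% (14.7 to 16.7%) of wt and 29.6% (28.3 to 31.0%) of GlaKO cells, and microglia, the resident immune cells of the brain, 8.22% (7.5 to 8.98%) and 16.04% (15.0 to 17.1%). Astrocytes were 7.24% and 9.68%, neurons 7.24% and 9.60%, oligodendrocyte precursors 6.90% and 9.88%, and T cells 3.12% and 4.61%. Among the cells outside the choroid plexus, 2825 in wt and 3711 in GlaKO, oligodendrocytes were 30.1% (28.4 to 31.8%) and 36.1% (34.5 to 37.6%), microglia 15.8% (14.4 to 17.1%) and 19.5% (18.2 to 20.8%), and T cells 5.98% and 5.6%. Astrocytes (13.9 and 11.8%), neurons (13.9 and 11.7%) and oligodendrocyte precursors (13.2 and 12.02%) were smaller shares of these cells in GlaKO, as were endothelial cells (2.58 and 0.108%) and pericytes (1.17 and 0.377%). Endothelial cells were 73 wt and 4 GlaKO cells (1.35% and 0.089%), border macrophages 34 and 47, pericytes 33 and 14, B cells 13 and 18 and ependymal cells 6 and 7. The unnamed cluster (45 wt and 35 GlaKO cells) had the endothelial markers Flt1 and Cldn5 among its leading genes, beside choroid plexus markers. Endothelial cells were 98 and 25 with Leiden at 0.5, and clusters of 75 and 5 and of 30 and 35 cells with Leiden at 2.0. The size of the endothelial difference thus depended on how such cells were named. The share of endothelial cells ranged from 0 to 0.984% in GlaKO across settings, and clustering the wt library alone gave 38.7% choroid plexus epithelium. In that clustering 534 wt cells with choroid plexus as best match stayed unnamed, since Igkc and Ighm were among their leading genes. Choroid plexus is attached to the hippocampus and is taken or left in dissection, and the enzymes, the density gradient and the 7-AAD gate can all set these shares.

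**Figure D2:**
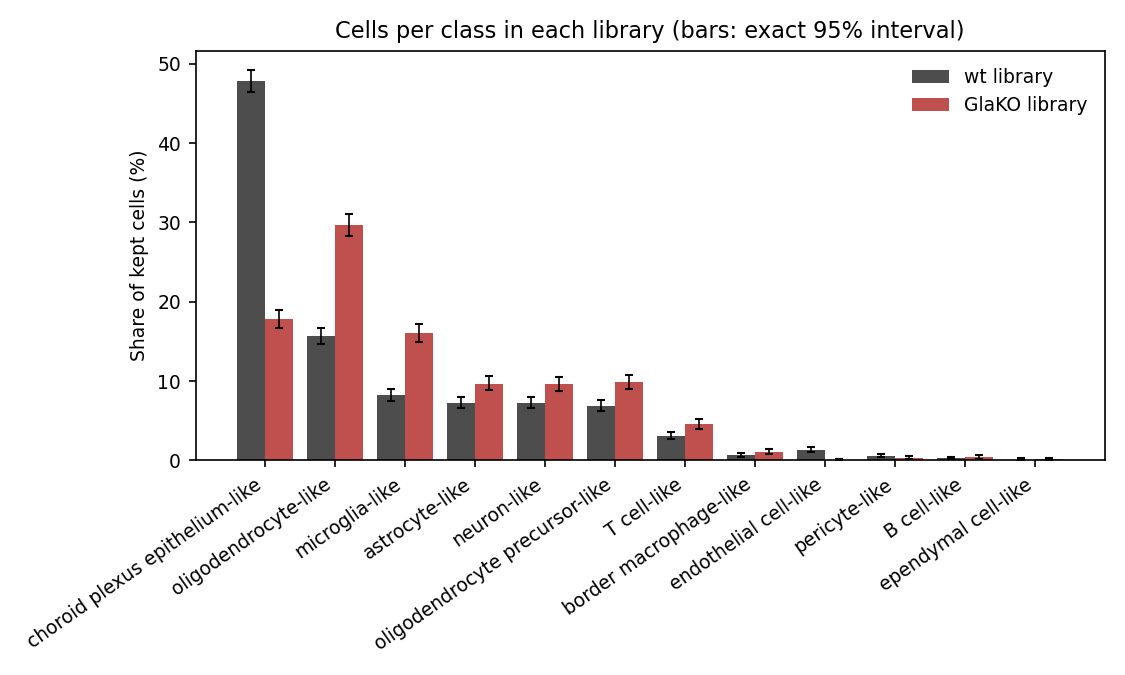
Share of kept cells (vertical axis, percent) in each class for the wt library (5417 cells) and the GlaKO library (4513 cells); error bars are exact Clopper-Pearson 95% intervals. Choroid plexus epithelium falls from 47.8% in wt to 17.8% in GlaKO, and oligodendrocytes and microglia are larger shares of the GlaKO library.

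Within choroid plexus epithelium, transcripts of lysosomal enzymes and their cofactors, which break down lipids, sugars and proteins, were lower in the GlaKO library. Of 34 measured members 30 had a ratio below 1 (26 by their interval), 6 of them by at least 1.5-fold, and the median log2 ratio was -0.38 (-0.47 to -0.33), below the middle 95% of random lists (-0.03 to 0.13). Gla was the lowest member and the protease Ctss, at 0.47, the highest. Ctss was among the leading genes of microglia clusters, and the microglial genes C1qa, C1qb and C1qc, summed, stood at 0.39 (0.23 to 0.54) in this epithelium. The 13 genes encoded by the mitochondrial genome, which code for subunits of the respiratory chain, all had ratios below 1, with an interval excluding 1 for 12 of them, and a median of -0.67 (-0.68 to -0.64), from -0.09 for mt-Nd4 to -1.46 for mt-Nd4l. Heat-shock genes, which encode protein chaperones, were higher in all 13 members, with a median of 0.43 (0.41 to 0.47). Among them Hspa1b stood at 1.95 and Hspa5 at 0.13. Immediate-early and dissociation-response genes, a sign of handling, had a median of 0.44 with 18 of 18 higher (12 by their interval), but only 1 reached 10% of its level in the highest class. Genes of the unfolded protein and integrated stress responses had a median of 0.24 (0.17 to 0.38), and 12 of 15 were higher (9 by their interval), led by Herpud1 at 1.05, a gene of protein quality control in the endoplasmic reticulum. Genes of cholesterol synthesis and uptake had a median of -0.19 (-0.24 to -0.04), with 14 of 22 lower (6 by their interval) and Mvd, an enzyme of the mevalonate pathway, highest at 0.56. The list of lysosomal membrane and acidification genes had a median of -0.08 (15 of 26 lower, 9 by their interval), with Atp6v0c at -0.74 and Npc1 at 0.31, and moved to -0.03 after thinning, inside the range of random lists. The disease-associated microglial list, which shares secreted and lysosomal genes with the lists above, was at -0.33 in this epithelium (11 of 14 lower, 10 by their interval), from Lgals3bp at -0.82 to Fabp5 at 0.74. The list of growth factors was at -0.26 (-0.34 to 0.00; 4 of 7 lower, 3 by their interval), with Pdgfb at 0.66 and Fgf2 at -0.47. GlaKO cells of this class were deeper (median 8612 against 5889 UMIs) and had a lower share of mitochondrial UMIs (1.20 against 2.48%). With cells of both libraries split equally over 5 parts of UMI depth, an alternative chosen after seeing the data, the lysosomal median moved to -0.07, the mitochondrial one to -0.35 and the stress-response one to 0.47, that of the disease-associated list to -0.07, inside the range of random lists, and that of growth factors turned to 0.09. Growth factors also turned to 0.03 with a minimum count of 20, and the stress-response median was 0.10 with each library clustered alone, both inside the range of random lists. Clustered alone, the wt library left 534 cells that best matched choroid plexus unnamed. In cluster 6 of this class the lysosomal median was -0.04 (-0.17 to 0.09).

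Single genes of the choroid plexus epithelium differed by more. Dlk1, a secreted and membrane-bound regulator of cell differentiation, had the highest log2 ratio at 4.08 (3.83 to 4.34), but its UMIs came from only 12 wt and 25 GlaKO cells, and it moved to 5.18 after thinning and 4.82 with the equal split over UMI depth. Cidea, which acts in lipid droplets, was higher by 2.45 (2.20 to 2.71). Prkar2b, a regulatory subunit of protein kinase A, stood at 2.26, Ceacam16 at 2.10, the stress kinase Mapk13 at 1.88, and Rab38, a small GTPase of lysosome-related organelles, at 1.86. Next came Tbc1d1 at 1.61, Det1 at 1.60, Wdfy1 at 1.56 and Asgr1 at 1.54. Lowest was Bex4 at -2.82 (-3.41 to -2.29), an X-linked gene at 136138996 to 136140443. Fabp3, a fatty acid carrier, was at -1.32, Oca2, a melanosome protein, at -1.23, the iron carrier Trf at -1.21 and Ccdc106 at -1.35. The level of Trf here was 11.9% of that in oligodendrocytes, where it was highest. Nme2 (-1.82), the histone gene Hist2h2aa1 (-1.71), Dynlt1b (-1.70) and Rnasek (-1.21) completed the group. Dynlt1b moved to -0.55 and Asgr1 to 0.86 after thinning, and Bex4 to -2.20 with the equal split over UMI depth. With each library clustered alone Prkar2b stood at 2.89, Mapk13 at 2.59, Tbc1d1 at 2.46 and Asgr1 at 2.34. The wt class then lacked 534 cells of an unnamed cluster that best matched choroid plexus. Hist2h2aa1, Nme2 and Dynlt1b have near-identical relatives in the genome, so their counts are uncertain.

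In oligodendrocytes the list of cholesterol synthesis and uptake, the pathway that feeds myelin membranes, had a lower median than random lists. The list's median was -0.22 (-0.30 to -0.10) and 15 of 21 members were lower (7 by their interval), while Lss, which makes lanosterol, was highest at 0.41. Random lists gave -0.05 to 0.13. Heat-shock genes had a median of 0.21 (0.17 to 0.25), with 11 of 12 higher (11 by their interval) and Hspa1b at 0.68, and immediate-early genes a median of -0.08 (-0.16 to -0.04), with 16 of 22 lower (8 by their interval) and Egr3, an activity-induced transcription factor, at -0.70. Sgk1, a kinase induced by glucocorticoids, was lower by a log2 ratio of -0.91 (-0.96 to -0.87) from 8365 wt and 8132 GlaKO UMIs. The detoxifying enzyme Gstp1 was at -0.90, and Ada, which deaminates adenosine, at -0.99. The lipid carrier Stard5 stood at -0.92, Grcc10 at -0.97, Rnasek at -1.13, Dynlt1b at -1.41, Nme2 at -1.84 and Hist2h2aa1 at -1.94, the last at 11.1% of its level in choroid plexus epithelium. The highest ratios were those of Ccdc152 (1.42), Lyrm7 (1.37), Nop2 (1.28), Dennd1b (1.27), Wdr74 (1.26), Tk2 (1.16), Jpt2 (1.12), Nmt2 (0.96), Pxdn (0.96) and Fam160b2 (0.94). The wt counts behind them ran from 19 to 48 UMIs, and when cells were thinned to 1000 UMIs Jpt2 turned to -0.17, Tk2 moved to 0.46, Lyrm7 to 2.34, Fam160b2 to 1.74 and Pxdn to 1.62.

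In microglia, the medians of MHC class I and inflammatory genes lay above those of random lists and that of the disease-associated state below. MHC class I genes had a median of 0.15 (0.02 to 0.20), 9 of 12 higher (3 by their interval), with H2-D1 at 0.25 and Psmb9 at -0.13. No member reached 1.5-fold, and the median moved to 0.03 after thinning and 0.07 with a minimum count of 500, inside the -0.12 to 0.09 of random lists. Inflammatory cytokines and NF-kB targets had a median of 0.17 (0.10 to 0.25), 12 of 17 higher (9 by their interval), from Ccl7, a chemokine that attracts monocytes, at 2.62 to Il6 at -0.48. Immediate-early genes were higher in 22 of 24 members (17 by their interval), with a median of 0.14 and Nr4a1 at 0.48, and heat-shock genes in 12 of 13 (10 by their interval), with a median of 0.22 and Hspa1b at 0.98. Both lists are known to respond to dissociation, and whether the higher inflammatory genes of the same cells are part of such a response was not tested. Ccl7 was also a leading gene of border macrophages with the wt library clustered alone. The disease-associated list was lower in 14 of 18 members (11 by their interval), with a median of -0.16 (-0.20 to -0.14) and Ccl6 at 0.54. Removing the 4% of barcodes with the highest doublet score moved it to -0.078, just inside the -0.08 to 0.06 of random lists, which ends the call in that setting. Its member Lpl, a lipase, was at -1.73 and at -1.10 without the top cell of each library. Spp1, or osteopontin, stood at -2.96, but 1 wt cell held 99.2% of the 1488 wt UMIs, and without the top cell of each library the ratio turned to 2.28. Paip2b (-1.33) likewise moved to -0.43, and Ccdc163 (2.87) to 0.82, without their top cells. Ddit4, a stress-induced inhibitor of mTOR signalling, was lower at -1.15 (-1.48 to -0.82), and Nme2 at -2.18. Rnaset2a (1.68) and Rnaset2b (1.38), near-identical copies of a lysosomal ribonuclease gene whose counts are uncertain, were higher, as were Adap2os (1.58), an antisense gene, and the X-linked Mid1 (1.53), a ubiquitin ligase of microtubules.

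In astrocytes the lysosomal enzyme list had a median of 0.13 (0.03 to 0.20), with 16 of 24 members above 1 but only 3 by their interval. The highest member was Ctss at 1.00, a protease gene that was among the leading genes of microglia clusters, and the lowest Hexa at -0.28. The microglial complement genes C1qa, C1qb and C1qc, summed, stood at 1.11 (0.81 to 1.42) in the same cells. The lysosomal median fell to 0.01 with a minimum count of 20 and to -0.01 with one of 500, inside the range of random lists. Unfolded protein and integrated stress response genes stood at 0.14, with 10 of 12 higher (4 by their interval) and Ddit3 at 0.43. Heat-shock genes stood at 0.11 (7 of 8 higher, 3 by their interval), with Hsph1 at 0.81, and 5 of 17 alternatives put this median inside the range of random lists, down to 0.03 with the equal split over UMI depth. Ntm, a cell adhesion molecule of synapses and axons, was higher at 1.04 (0.94 to 1.15) from 1015 wt and 2675 GlaKO UMIs. Rnaset2a was at 1.49, the translation factor Pabpc1 at 1.22, the kinase subunit Csnk2a1 at 1.05 and Ino80b at 0.97 (1.77 after thinning). Lower were Hist2h2aa1 (-1.72), Nme2 (-1.30), Lrrcc1 (-0.97), Mapk1ip1 (-0.92) and Isca1 (-0.85), which acts in iron-sulfur cluster assembly.

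In neurons, synaptic genes were higher, 16 of 20 of them (10 by their interval), with a median of 0.18 (0.11 to 0.23), Nrxn3, a presynaptic adhesion molecule, at 0.66 and the glutamate receptor subunit Grin2a at -0.15. Cholesterol synthesis and uptake stood at 0.19 (0.02 to 0.28), 12 of 15 higher but only 1 by its interval, with Srebf2 at 0.45 and Ebp at -0.35. The transcription factors Neurod6 (1.27) and Tshz2 (1.40), and Ntm (1.48), Pcdh11x (1.60) and Spock1 (1.30), all proteins of the neuronal surface or matrix, were the highest single genes. Clusters 9, 12 and 17 made up this class, and cluster 17 held 11.2% of wt and 21.7% of GlaKO neurons. Given equal weights for the clusters, the synaptic median moved to 0.09, that of cholesterol genes turned to -0.09, and Neurod6 moved to 0.47, Tshz2 to 0.63, Spock1 to 0.68, Pcdh11x to 1.00 and Ntm to 0.84. Ntm stood at 2.28 after thinning. The cholesterol median lay inside the range of random lists in 5 of 16 alternatives. Lower were Zfp287 (-1.76) and the calcium-binding protein gene Calb2 (-1.69), of which 1 wt cell held 71.9% and 69.0% of the wt UMIs, and which moved to -0.01 and -0.21 without their top cells, while thinning moved Zfp287 to -4.79. Nme2 (-1.29), Rnf121 (-1.05) and Zmym6 (-1.04) were lower too, and Zmym6 turned to 0.03 after thinning.

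Oligodendrocyte precursors had higher transcripts of Bmp4 (1.74, 1.20 to 2.33), a signal made by precursors that commit to differentiate, and of Chn2 (1.79), Mid1 (1.5), Rnaset2a (1.45, or 2.14 after thinning) and the sphingomyelinase gene Smpd3 (1.25). A single GlaKO cell held 38.1% of the Bmp4 and 34.4% of the Chn2 UMIs, and with each cell weighted equally the ratios were 0.86 and 0.80. Histone genes made in dividing cells were lower: Hist1h2ap at -3.21 (-3.65 to -2.79), or -2.54 without its top cells, and Hist1h2ae at -1.26, or -0.25 after thinning, both members of a family of near-identical copies. Nme2 (-1.55), the X-linked Rtl4 (-1.29) and Blvra (-0.99), which makes bilirubin, were also lower. Neurogenesis genes had a median of 0.20 (0.02 to 0.33), 7 of 8 higher (3 by their interval), with Dcx at 0.46 and Hopx at -0.31, and this median turned to -0.039 after thinning. Lysosomal membrane and acidification genes stood at -0.13 (-0.17 to -0.03), with 14 of 21 lower (6 by their interval) and Atp6v0c at -0.64. With the equal split over UMI depth this median moved to -0.03 and the neurogenesis one to 0.01, both inside the range of random lists.

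T cells of the GlaKO library had more transcripts of the interferon-stimulated genes that could be measured, 5 of the 20 on the list. All 5 measured members were higher (5 by their interval), with a median of 0.64 (0.39 to 0.79) against -0.18 to 0.34 for random lists, and the antiviral protein gene Isg15 was highest at 1.00. The microglial genes C1qa, C1qb and C1qc, summed, were also higher in these cells, at 1.48 (1.16 to 1.81) from 100 wt and 447 GlaKO UMIs. Plac8, expressed in recently activated lymphocytes, was at 2.44 (1.71 to 3.26) and Rnaset2b at 2.35 (3.40 after thinning). Histone genes went the other way from the precursors: Hist1h1b (3.30, from 5 wt and 11 GlaKO cells), Hist1h2ae (2.23) and Hist1h2ap (1.87) were higher, but moved to 1.59, 1.27 and 0.69 with each cell weighted equally. The inhibitory receptor gene Pdcd1, a marker of antigen-experienced T cells, was lower at -1.06 (-1.38 to -0.73), as was Nme2 (-1.50). Ccl3 (-2.09) and Hilpda (-1.26) were lower, but moved to -0.96 and -0.53 without their top cells.

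Nuclear-encoded respiratory chain genes, which build the mitochondrial complexes that make ATP, had lower medians in 6 of 7 classes: oligodendrocytes -0.12 (31 of 34 lower, 19 by their interval), microglia -0.14 (33 and 17 of 34), astrocytes -0.17 (32 and 21 of 34), neurons -0.11 (29 and 13 of 34), oligodendrocyte precursors -0.14 (30 and 13 of 34) and T cells -0.11 (26 and 4 of 32). With doublets kept the medians of T cells (-0.02) and neurons (-0.09) lay inside the range of random lists. In choroid plexus epithelium the median was -0.02. Atp5g1, an ATP synthase subunit, was the lowest member in oligodendrocytes, microglia, astrocytes, oligodendrocyte precursors and T cells, at -0.61 in astrocytes, and in neurons Sdhc was lowest at -0.36. Sdha, at 0.14 in oligodendrocytes, Cox6a1, at 0.16 in microglia, and Cox5a, at 0.24 in T cells, were the highest there. Short transcripts had lower ratios than long ones in every class, and these genes are short (median 627 nucleotides against 2180 for all genes). Against random lists matched on length as well, the median stayed below the 2.5th percentile in 5 of the 6 classes, all but neurons. Summed UMIs of choroid plexus markers in these 6 classes were also lower in GlaKO, by log2 ratios from -0.65 in neurons to -2.29 in T cells. With a matching share of the choroid plexus profile subtracted, the medians lay between -0.15 and -0.02, and 4 of 6 stayed below the 2.5th percentile. Among these 4 were T cells, at -0.02 (percentile 1.65), a class in which all compared genes had a median of 0.06. The medians of mitochondrially encoded genes followed no common direction. They were higher in microglia (median 0.11, 12 of 13 higher, 8 by their interval) and lower in oligodendrocyte precursors (-0.15, 10 of 13 lower, 6 by their interval). In the precursors the median moved to -0.04 with equal weights for the clusters, inside the range of random lists. In both classes, as in choroid plexus epithelium, mt-Nd4 was the highest member and mt-Nd4l the lowest. They stood at 0.47 and -0.71 in microglia and at 0.51 and -0.94 in oligodendrocyte precursors. The source of this gap, which recurred over classes of the same 2 libraries, was not tested.

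A few genes differed in one direction by at least 1.5-fold in all 7 compared classes. Btg1, an inhibitor of proliferation, was higher by log2 ratios from 0.65 in T cells to 1.06 in choroid plexus epithelium, and Slc38a2, an amino acid transporter induced by stress and starvation, from 0.59 in oligodendrocyte precursors to 1.59 in astrocytes. Nme2, a nucleoside diphosphate kinase, was lower from -1.29 in neurons to -2.18 in microglia, and Gstp1 from -0.62 in oligodendrocyte precursors to -0.94 in choroid plexus epithelium. Under alternatives each of the 4 fell below 1.5-fold in single classes: after thinning Nme2 stood at -0.44 in neurons and Gstp1 at -0.385 in oligodendrocyte precursors, with TMM Slc38a2 at 0.58 in oligodendrocytes and 0.53 in T cells, and with centring on all genes Btg1 at 0.58 in T cells. Thinning moved Nme2 to -0.70 in oligodendrocyte precursors, -2.62 in T cells and -3.18 in microglia. Counts of Nme2 and Gstp1 are uncertain, since both have close relatives or pseudogenes that share reads. Several of these levels were low against the class with the highest level: Btg1 reached 2.0% of it in choroid plexus epithelium and 3.9% in oligodendrocytes, Slc38a2 3.3% in choroid plexus epithelium and 8.6% in astrocytes, and Gstp1 4.5% in microglia, 8.2% in astrocytes and 9.3% in oligodendrocyte precursors.

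Glycosphingolipid and ceramide synthesis genes, which make the lipids upstream of alpha-galactosidase A, had medians from -0.03 in microglia to 0.16 in astrocytes, and autophagy genes from -0.04 in astrocytes to 0.11 in choroid plexus epithelium, all within the middle 95% of random lists. The same held for homeostatic genes in microglia (0.05) and for myelin genes in oligodendrocytes (0.03, 11 of 19 higher). A4galt, a member of the glycosphingolipid list, was not listed in both libraries and so was not measured.

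**Figure D3:**
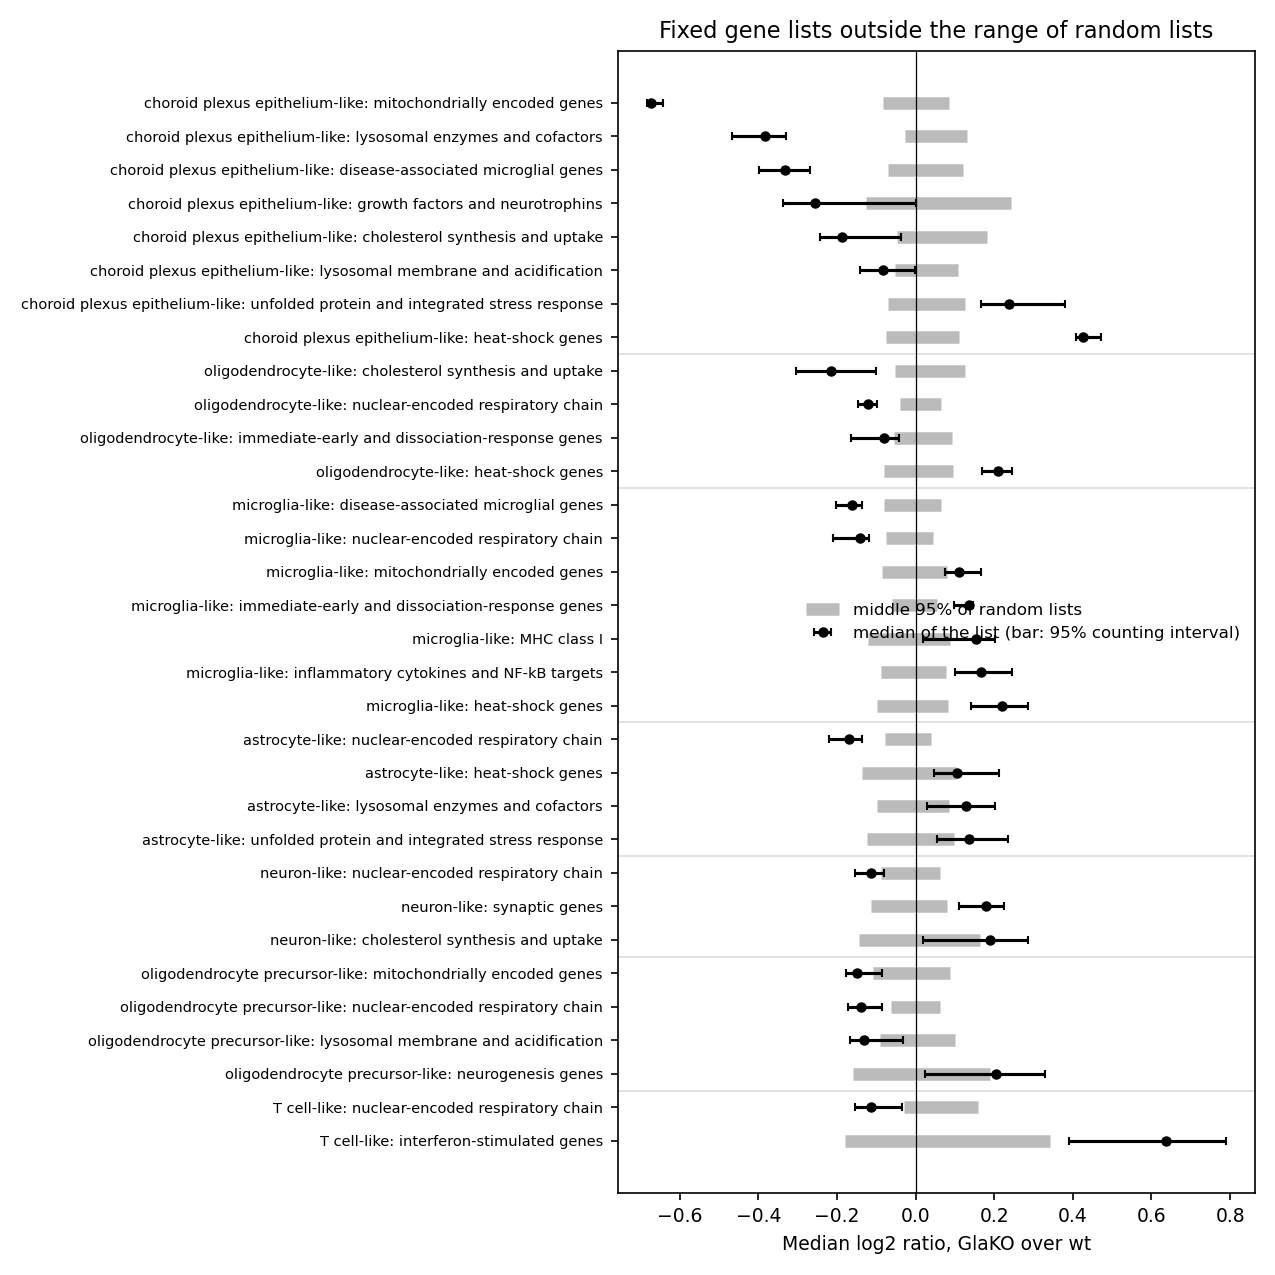
Median log2 ratio of GlaKO over wt (horizontal axis) for each described gene list in each class; points are medians, bars 95% counting intervals, and grey bands the middle 95% of random lists matched on mean expression. Mitochondrially encoded genes (-0.67) and lysosomal enzymes (-0.38) of the choroid plexus epithelium lie farthest to the left, and interferon-stimulated genes of T cells (0.64) farthest to the right.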

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

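Alternatives chosen after the data were seen were the removal by doublet score, equal makeup of clusters, the equal depth split, and leaving out single cells or 1 barcode rich in erythroid UMIs. Over all alternatives 123 of 128 Gla ratios, 465 of 542 list medians, 1866 of 1982 gene ratios and 102 of 112 shares stayed within their counting interval, and 3, 5, 4 and 0 changed sign. The 3 Gla ratios were all in astrocytes, and 2 of the 5 medians were those of growth factors in choroid plexus (0.027 with a count of at least 20, 0.088 with the depth split), 2 results whose interval includes or touches equal levels. The filter on cells removed no barcode, so keeping all barcodes tests nothing, and a count minimum cannot move the ratio of a single gene. The totals above count these settings as unmoved. For keeping all barcodes these are 8 Gla ratios, 32 list medians, 114 gene ratios and 16 shares. For the minima of 20 and 500 they are 8 and 1 Gla ratios and 114 and 44 gene ratios. No paired analysis was possible because each genotype has 1 library. Depth limits Gla outside the choroid plexus, where single compared classes hold 6 to 64 UMIs per library.

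The equal depth split moved 18 of 32 list medians out of their interval, and thinning moved 48 of 114 gene ratios out of theirs and turned 2 more, with 24 of the 114 changing by at least 1.5-fold. Of the 32 list medians 14 fell inside the middle 95% of random lists, taken from the unchanged data, in at least 1 alternative, and 18 in none. The larger changes follow by setting, with no test of their cause. With the 4% of barcodes of highest doublet score removed, Spp1 in microglia turned to 3.99 and the disease-associated microglial list moved to -0.078. With doublets kept, that list stood at -0.12, respiratory chain genes in T cells at -0.022, and endothelial cells at 2.17% of wt and 0.984% of GlaKO cells. Endothelial cells were 1.81 and 0.554% with Leiden at 0.5, 1.94 and 0.886% with Leiden at 2.0 and 1.87 and 0.846% under the stricter filter. With each library clustered alone, wt choroid plexus was 38.7% and GlaKO endothelial cells 0%, and medians were 0.49 for heat-shock, -0.66 for lysosomal enzyme and -0.94 for mitochondrially encoded genes in choroid plexus and 0.23 for synaptic genes in neurons. There 534 wt cells with choroid plexus as best match stayed unnamed, so these choroid plexus values compare a wt class that lacks them. TMM gave -0.99 for Gla over all cells and 0.34, -0.47 and -0.76 for the same 3 choroid plexus lists in that order. Centring on the median of all genes gave -1.01 for Gla over all cells, 0.36 for heat-shock and -0.73 for mitochondrially encoded genes, and equal weight per cell gave -0.63 for the latter. Thinning to 1000 UMIs gave Gla ratios of 1.17 in astrocytes, -1.93 in choroid plexus and -0.84 in oligodendrocyte precursors, and turned Jpt2 to -0.17, Zmym6 to 0.026 and the neurogenesis list to -0.039. It moved the cholesterol list in oligodendrocytes to -0.35, the disease-associated list in microglia to -0.12, and lysosomal and mitochondrially encoded genes in choroid plexus to -0.33 and -0.62. Equal makeup of clusters turned cholesterol genes in neurons to -0.094 and moved synaptic genes to 0.094 and choroid plexus heat-shock, lysosomal and mitochondrially encoded genes to 0.39, -0.25 and -0.54. The equal depth split moved these 4 to 0.10, 0.47, -0.073 and -0.35, and the disease-associated list to -0.13 in microglia and -0.067 in choroid plexus. It left 0.008 for neurogenesis and -0.027 for lysosomal membrane genes in oligodendrocyte precursors and 0.034 for heat-shock genes in astrocytes. A count of at least 500 turned lysosomal enzymes in astrocytes to -0.009, and leaving out the top cell of each library turned Spp1 to 2.28. Requiring 30% rather than 10% of the highest class kept 14 of 20 named genes in choroid plexus, 10 of 20 in oligodendrocytes and 6 to 8 of 10 in the others.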

Other observations

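All tests below were chosen after the result was seen, except those of transcript length and of free choroid plexus RNA over the 6 classes and that of transcript length for lysosomal genes.

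MHC class II genes, which present antigen to helper T cells, stood higher in the microglia class of the GlaKO library. Cd74, the invariant chain, had 163 wt and 2807 GlaKO UMIs, a log2 ratio of 3.15 (2.92 to 3.39), and H2-Ab1 36 and 636 UMIs, a ratio of 3.19 (2.70 to 3.72). H2-Aa (4 and 446 UMIs) and H2-Eb1 (5 and 540 UMIs) went the same way at 5.85 (4.48 to 7.73) and 5.80 (4.57 to 7.43), H2-DMa stood at 0.50 (0.33 to 0.68), and H2-DMb1 at 0.03 with an interval including equal levels. In the GlaKO library few cells held most of the Cd74 UMIs: 39 of 724 microglia had at least 10, against 2 of 445 in wt, where 78 cells held the 163 UMIs. Border macrophages, a class led by Cd74, were 34 wt and 47 GlaKO cells, but 52 and 69 with Leiden at 0.5. The border between these classes thus moved with the setting, and whether those 39 cells are microglia was not tested. Cd74 was seen in 17.5% of wt and 26.1% of GlaKO microglia, and in 5.17 and 12.98% after thinning to 1000 UMIs, against thinned shares of 0.35 and 0.75% in oligodendrocytes, which should lack it (median depths 5372 and 6436 UMIs in microglia, 5819 and 6708 in oligodendrocytes). Most members lay below 10% of their level in the highest class, so the list was not described among the comparisons.

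Genes of dividing cells moved apart between classes, on the 2 of 6 markers, Cdk1 and Cenpf, that are listed in both libraries. Their summed UMIs were 64 in wt and 24 in GlaKO oligodendrocyte precursors (-1.95, -2.69 to -1.25) and 2 and 48 in T cells (3.90, 1.97 to 6.99), with at most 11 cells behind each sum. Hemoglobin and other erythroid genes, summed, were higher in GlaKO in the 6 classes other than oligodendrocytes by 1.61 to 2.36. In oligodendrocytes 1 GlaKO barcode held 7961 of 8819 erythroid UMIs, and without it the ratio was 2.06 (1.77 to 2.35). Myelin genes, summed, were also higher in GlaKO microglia (0.73), astrocytes (0.80), neurons (1.01), T cells (1.15) and oligodendrocyte precursors (0.52). Myelin UMIs were seen in 90.8% of wt and 99.5% of GlaKO neurons and in 92.9 and 100% of T cells. Oligodendrocytes were 15.7% of wt and 29.6% of GlaKO cells. These sums may thus reflect RNA released by oligodendrocytes and not a change in the other cells, which was not tested. In choroid plexus epithelium the sum of myelin genes did not differ (0.00, -0.03 to 0.03), while 15 of 16 single genes were higher (median 0.77) and Trf, with 12096 of the 35754 wt UMIs, was lower.

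Nuclear-encoded respiratory chain genes had lower medians in 6 of 7 classes. Short transcripts lower in the GlaKO library were argued against as the whole cause by 5 of 6 classes. In these the median stayed below the 2.5th percentile of length-matched lists, but in neurons it lay at percentile 10.16. Matching used 5 parts of length, and the shortest had median lengths from 645.5 nucleotides in T cells to 752.5 in neurons. The list's median of 627 is shorter, so some effect of length may remain in the comparison. Less free choroid plexus RNA in the GlaKO library was also argued against as the whole cause, but only narrowly. This rested on 4 of 6 classes after subtraction, the fewest that could do so by the bound set beforehand, and the medians shrank. The 4 included T cells, whose median of -0.02 was near equal levels and lay at percentile 1.65. All compared genes of that class had a median of 0.06. In microglia and neurons the lower percentile was 17.01, so there this source may account for the pattern. Both sources acting together were not tested, and an effect of genotype stays open, untested.

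Lysosomal enzyme genes were lower in GlaKO choroid plexus epithelium, at a median of -0.38. Transcript length (percentile 0.0 among length-matched lists) and the makeup of clusters (percentile 0.0 with equal weights, 67.0% of the distance from random lists left) were argued against as the whole cause. Clusters 2, 3 and 5 alone had medians of -0.25, -0.31 and -0.27, but cluster 6, with 27.2% of wt and 30.6% of GlaKO cells of the class, -0.04 (-0.17 to 0.09), which includes equal levels. Much of the difference went along with depth. Within each library all 34 members were lower in the deepest than in the shallowest of 5 parts. An equal depth split left 26.9% of the distance, a median of -0.07 against -0.05 to 0.14 for random lists. That is still at percentile 0.51, or 1.2 with 10 parts, under the bound of 2.5, so depth as the whole cause is argued against only narrowly, and a bound on the distance left, tried after these values were seen and then dropped, would have favoured depth. Depth may follow cell state as well as capture, so an effect of genotype on either stays open, untested.

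Choroid plexus epithelium was 47.8% of wt and 17.8% of GlaKO cells. Class naming, clustering or the cell filter alone would leave free choroid plexus RNA alike, but its markers in the 6 other classes had a median log2 ratio of -1.37. The amount of choroid plexus tissue in the dissected sample and an effect of genotype cannot be told apart with 1 library per genotype.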
